A study of Mus musculus with 2 samples.

How the data were processed

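The study measured transcript levels in spleen cells of mice on a 1-colour Illumina bead array. Cells carrying both B220, a CD45 isoform of B lineage cells, and CD138, the syndecan encoded by Sdc1 that marks antibody-secreting cells, were collected by flow sorting, per the series' design text. There were 2 arrays, 1 from K/BxNsf mice and 1 from control K/BxN mice, and the labels name the sorted cells plasma cells. Groups were taken from the sample titles. The labels give an age of 5 weeks for K/BxNsf and 8 weeks for K/BxN, so age differed together with the group, and they give male sex for both. How many animals went into each array is not given in the sources used here.

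Total RNA was extracted with Trizol, cleaned on RNeasy columns and amplified to biotinylated cRNA with an Ambion kit for Illumina arrays, per the labels' protocols. Scanner output was handled in GenomeStudio 2009.2, per the submitters' processing notes. The authors deposited a table of probe signal intensities for 25697 probes before normalization between arrays, with a detection p-value for each probe and array, per the file headers. Whether a background had been subtracted in the scanner software is not given in the sources used here; the lowest intensities were 92.9 on the K/BxNsf array and 96.5 on the K/BxN array, so no subtraction to 0 was visible. The authors also deposited log2 values of the same arrays. When these were set against the signal columns, they had a value for the 12553 probes with a detection p below 0.05 on at least 1 array and were blank for the other 13144. Their sorted values matched log2 of the mean of the ordered signals of the 2 arrays to within 1.999e-04, which is quantile normalization followed by log2, and the rank correlation of each column with its own signal column was 1. Both columns had a median of 8.46. The scale of the deposited log2 values was thus recovered from the values themselves and is not stated in a label.

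The deposited intensities were background-corrected and normalized with limma 3.58.1 in R 4.3.3. The correction was the normexp model with the background inferred from the detection p-values and an offset of 16, followed by quantile normalization and log2. The background estimated this way had a mean of 131.2 and an SD of 13.4 on the K/BxNsf array, and a mean of 140.8 and an SD of 16.5 on the K/BxN array. A probe counted as measured on an array where its detection p was below 0.01. Each gene was represented by its brightest probe among those measured on both arrays, and its log2 difference is K/BxNsf minus K/BxN. The offset shrinks the folds of dim genes. Quantile normalization gives both arrays 1 common distribution of values, although 33.5% of the probes were measured on the K/BxNsf array and 38.7% on the K/BxN array. Dim signals on the K/BxNsf array are thereby raised relative to those on the K/BxN array, so the sign of a log2 difference can be opposite to the order of the signals before scaling. Together with background correction, this can also make a fold higher in K/BxNsf larger than the ratio of the signals. Cd8b1, for example, was 5.75-fold higher at signals of 605.9 in K/BxNsf and 301.5 in K/BxN. A gene with measured probes on 1 array only has a bound in place of a fold. The bound sets the measured value against the higher of the dim probe's own value and the lowest value among probes measured on the dim array, all after normalization. It is written as at least N-fold, and no fold is given where the bound was under 1. Near background such a bound can exceed the ratio of the signals before scaling, or go against their order. S1pr2 had signals of 185.9 in K/BxNsf and 196.6 in K/BxN, and a bound of 1.80-fold higher in K/BxNsf.

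Probe names came from a platform annotation, updated through Entrez identifiers to the RefSeq genes of mouse assembly GRCm38.p6. Of the probes, 23978 had 1 gene symbol, 0 had several and 1719 had none and are unnamed here. The named probes covered 16593 genes. The array files name no genome build, so no coordinates are given. No probe was named as an immunoglobulin gene in the annotation used, so the list of immunoglobulin genes fixed for this comparison had 0 genes with a probe and no value. A few listed genes, Mki67 among them, had no named probe and were not used here.

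With 1 array per group there are no residual degrees of freedom, so no test between the groups was run and no p-value is given for any difference. Values describe these 2 arrays. Genes were counted as apart where the log2 difference was at least 1 in size, which is 2-fold. The only internal measure of error was the agreement of different probes of the same gene. Over 992 genes with exactly 2 measured probes, the SD of the difference between their log2 differences was 0.66, or 0.47 per probe. This covers probe error only, and not the spread between mice, sorts or arrays. Among the 435 of these genes with a probe at least 2-fold apart, the probes had the same sign in 403, or 92.6%. Of the 123 genes named by the rule below, 13 had 2 or more measured probes, and in 0 of the 13 did the probes differ in sign. The widest spreads among the 13 were those of Sel1l, from 1.85 to 3.69, Cd28, from 1.67 to 3.12, Creb3l2, from 2.04 to 3.03, and Lyz2, from 0.86 to 1.76.

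Before the data were examined, 27 gene lists were fixed, along with the rules for naming genes, the settings and 10 alternatives to them. Of the lists, 17 hold gene programmes and the others markers of cell types that the spleen or the sort could hold. For each list with at least 5 measured genes, the median log2 difference was set among the medians of 10000 random lists of the same size, with each gene replaced by one from the same of 20 bins of mean expression. The range given after a median is its 95% interval from order statistics over the measured genes, which covers the choice of genes and no spread between mice. Percentiles were computed for 19 lists. Named genes are the 12 highest and the 12 lowest by log2 difference among genes measured on both arrays, at least 2-fold apart and with the brighter value at or above the median. To these were added the 5 largest bounds in each direction among genes measured on 1 array, up to 4 genes per list with the largest difference or bound, and a short fixed set (Sdc1, Ptprc, Prdm1, Xbp1, Foxp3, Tnfrsf17, Cd274, Il6, Cd28, Bcl2). Other genes named as list members were chosen after their values were seen. Some gene families grouped by symbol stem are not reported here.

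The alternatives were no background correction, normexp on the signals alone with an offset of 50, an offset of 50 in the main correction, median centring or cyclic loess in place of quantile normalization, the deposited log2 values, a detection p below 0.05, measurement on at least 1 array, no filter on dim probes, and the mean of a gene's probes. A requirement of a signal at least 2 times the background mean on both arrays was added after the data were seen. The procedure was tested on simulated data built from the K/BxN signals with 200 genes changed by known folds and an assumed noise SD of 0.2 on the log2 scale. Over the 6903 genes measured in that simulation of K/BxNsf against K/BxN, 100% of the genes changed 4-fold or 8-fold upward, and 100% of those at 0.25 of their level, passed the 2-fold threshold. Of genes changed exactly 2-fold upward, 37.5% passed, and of those at 0.5 of their level 35.9%, while 0.209% of unchanged genes did. These shares leave out genes not measured on both simulated arrays. Of 40 genes at 0.25 of their level 35 were measured on both, and of 40 at 0.5 of their level 39 were. The noise was assumed for each array, and the SD per probe of 0.47 found above for a log2 difference was not used. Both simulated arrays came from the K/BxN signals, so the unlike shares of measured probes were not simulated. These rates hold for that setting and are not rates of false calls on these arrays. Lists, percentiles and counts were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.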

Results

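Expression was profiled in sorted splenic B220+CD138+ cells from K/BxNsf mice and from their K/BxN controls, with 1 array per group. K/BxN mice are a model of spontaneous, autoantibody-driven arthritis, and the labels do not spell out the sf suffix. The comparison addresses how the cells sorted by this gate differ between these mice, which were 5 weeks old for K/BxNsf and 8 weeks old for K/BxN. It does not establish that both sorts held antibody-secreting cells alone. Since there are no replicates, no difference below has a replicate check, and the number of arrays limits the precision. On the K/BxNsf array 8616 of 25697 probes were measured above background and the median signal was 143.7. On the K/BxN array 9956 probes were measured and the median signal was 161.4.

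The K/BxNsf array carried more transcript of the antibody secretion programme and far less of the B cell and MHC class II programmes than the K/BxN array. Fkbp11, a peptidyl-prolyl isomerase of the secretory pathway, was 12.1-fold higher in K/BxNsf, and Xbp1, a transcription factor of plasma cell differentiation and secretion, was 3.72-fold higher. In the other direction Fcmr, the Fc receptor for IgM, was 136-fold lower in K/BxNsf, and Blk, a Src family kinase of B cells, was 81.4-fold lower. Fcer2a, which encodes the low-affinity IgE receptor CD23, was measured on the K/BxN array alone and was at least 155-fold lower in K/BxNsf. Of 5885 genes measured on both arrays, 1140 were at least 2-fold higher and 839 at least 2-fold lower in K/BxNsf, so 57.6% of the genes apart were higher. With median centring in place of quantile normalization the counts were 515 higher and 1925 lower, so 21.1% were higher, and the median log2 difference of all genes was -0.52 against 0.13. Across the 5885 genes, which are not independent replicates, the normalized log2 values of the arrays had a Pearson r of 0.79. Granulocyte marker genes were also higher in K/BxNsf, with a median log2 difference of 2.86 over 8 genes. A further 347 genes were measured on the K/BxNsf array alone and 1050 on the K/BxN array alone.

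**Figure D1:**
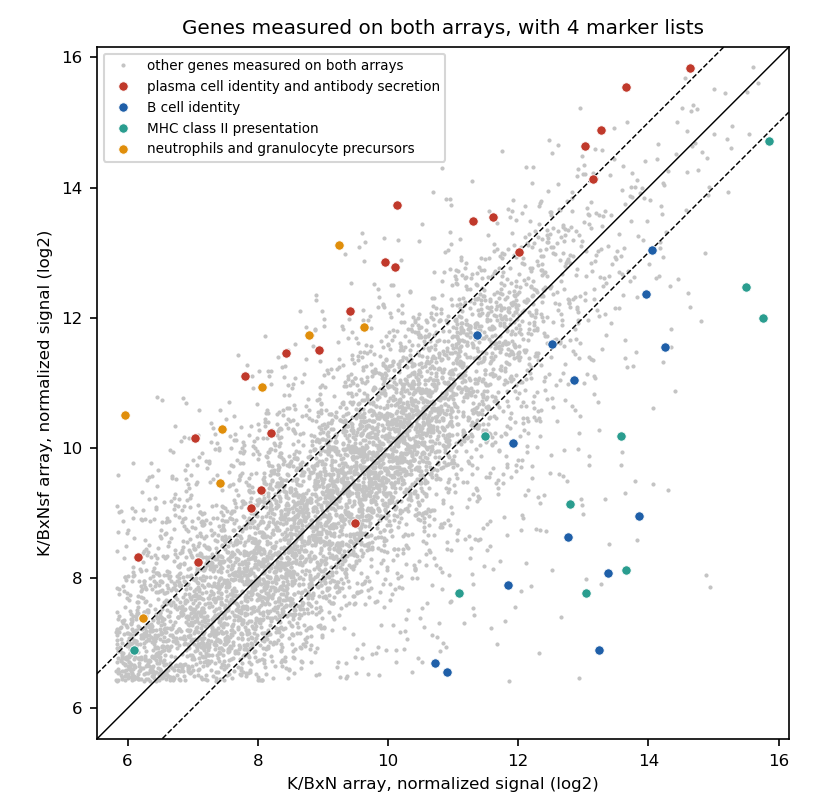
Normalized log2 signal of the 5885 genes measured on both arrays, K/BxN on the horizontal axis and K/BxNsf on the vertical axis (1 array each), with the genes of 4 lists in colour, a solid line at equal values and dashed lines at 2-fold. Plasma cell genes lie above the solid line except for 1 of 22, and B cell and MHC class II genes lie mostly below the lower dashed line.

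Genes of plasma cell identity and antibody secretion were higher in K/BxNsf as a group. Of 22 measured genes, 20 were at least 2-fold higher and 0 were at least 2-fold lower, with a median log2 difference of 1.98 (1.20 to 2.68). Under median centring 17 were at least 2-fold higher and 1 lower. After Fkbp11 the largest differences were in Fndc3b, at 9.82-fold, in Cd28, a costimulatory receptor also found on plasma cells, at 8.67-fold, and in Creb3l2, a transcription factor of secretory capacity, at 8.18-fold. Tnfrsf17, which encodes the plasma cell survival receptor BCMA, was 4.05-fold higher, with signals of 985.3 and 564.7. Jchain, the joining chain of polymeric antibodies, was 4.45-fold higher at dim signals of 332.4 and 222.3, and Mzb1, an endoplasmic reticulum protein of antibody-secreting cells, was 2.29-fold higher at signals of 63522 and 25522. Tnfrsf13b, the receptor TACI, was the 1 gene of the list measured on both arrays that was lower after scaling, by 1.56-fold. Before scaling Sub1 also had the lower signal in K/BxNsf, 320.3 against 323.5, although it was 2.25-fold higher after scaling. Cd93 was measured on the K/BxN array alone, at 223.6 against 166.3, which gave no fold. Eaf2 was measured on the K/BxNsf array alone, with a bound after scaling of 2.94-fold higher at signals of 229.3 and 161.4. Prdm1, which encodes Blimp-1, was not above background on either array, with signals of 161.8 in K/BxNsf and 146.8 in K/BxN. None of 10000 random lists matched on expression had a median as high as that of the list (0 above).

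Sdc1, which encodes the sorting marker CD138, had nearly equal signals before scaling, 491.7 in K/BxNsf and 472.0 in K/BxN. Quantile normalization placed it at a log2 difference of 1.18, and median centring at 0.41, which is under 2-fold. A second Sdc1 probe stood at 2.01 under quantile normalization. Ptprc, whose product includes B220, was 2.40-fold lower in K/BxNsf at dim signals of 203.8 and 583.5. Its log2 difference was -0.75 with no background correction, also under 2-fold, and -2.09 with median centring.

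Genes of protein folding and quality control in the endoplasmic reticulum were higher in K/BxNsf along with the secretory genes. Of 21 measured genes of the unfolded protein response list, 19 were at least 2-fold higher and 0 lower, with a median of 1.502 (1.30 to 2.04). Under median centring 15 were at least 2-fold higher and 1 lower. Sel1l, an adaptor of endoplasmic reticulum-associated degradation, was 12.9-fold higher, the chaperone gene Hyou1 6.89-fold, Edem1, which acts in disposal of misfolded glycoproteins, 5.52-fold, and the co-chaperone gene Dnajb9 5.04-fold. Sel1l signals were 9332 against 1225, and its 2 probes stood at log2 differences of 1.85 and 3.69. Ddit3, which encodes the stress-linked transcription factor CHOP, was 1.82-fold lower. Genes of the amino acid response list were also higher, 12 of 16 by at least 2-fold and 0 lower by as much, with a median of 1.68 (0.94 to 3.08). Among them Slc7a5, a large neutral amino acid transporter, was 11.5-fold higher, Asns, asparagine synthetase, 8.94-fold, the transcription factor gene Atf5 8.64-fold and Chac1, a glutathione-degrading enzyme, 8.45-fold. Atf4 itself differed by a log2 value of 0.11, with signals before scaling of 909.8 in K/BxNsf and 1551 in K/BxN. For both lists 0 of 10000 random lists had a higher median. Under median centring the amino acid median was 0.97, or 1.49 above the median of all genes, and 8 of the 16 were at least 2-fold higher.

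Genes of B cell identity were lower in K/BxNsf. Of 14 genes measured on both arrays, 12 were at least 2-fold lower and 0 higher, with a median log2 difference of -3.33 (-4.91 to -1.01), and 7 more were measured on the K/BxN array alone. After Fcer2a and Blk, the largest were Cd22, an inhibitory receptor of B cells, at least 70.2-fold lower, and Ciita, the master regulator of MHC class II genes, at least 65.0-fold lower. On the K/BxN array the signals of Fcer2a and Cd22 were above those of 99.6% and 98.6% of probes. The plasma cell genes Xbp1 and Mzb1 were likewise above 99.5% and 99.8% of probes on that array. The components of the B cell receptor were closer together, with Cd79a 6.54-fold and Cd79b 2.01-fold lower. Blnk, an adaptor of B cell receptor signalling, was 1.29-fold higher after scaling alone, since its signals before scaling were 2842 in K/BxNsf and 3449 in K/BxN. Cd24a was measured on the K/BxNsf array alone. With signals at least 2 times the background on both arrays, 11 genes were left and the median was -1.84.

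The MHC class II presentation genes were lower by a similar size. Of 10 measured genes, 9 were at least 2-fold lower in K/BxNsf and 0 higher, with a median of -3.36 (-5.28 to -1.15). H2-Ob and H2-Oa, the chains of the peptide-loading modulator H2-O, were 46.5-fold and at least 67.4-fold lower, and H2-DMb2, a chain of the peptide loader H2-DM, was 38.9-fold lower. The classical chains H2-Ab1 and H2-Eb1 had signals of 4977 and 3515 in K/BxNsf against 44389 and 50134 in K/BxN. Cd74, the invariant chain, was 2.21-fold lower and was bright on both arrays, at 27283 and 54309. Ctss, the protease that cleaves the invariant chain, was 1.74-fold higher after scaling alone, at signals close to background of 197.4 in K/BxNsf and 216.4 in K/BxN. For the B cell list and for this list, 0 of 10000 random lists had a lower median.

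**Figure D2:**
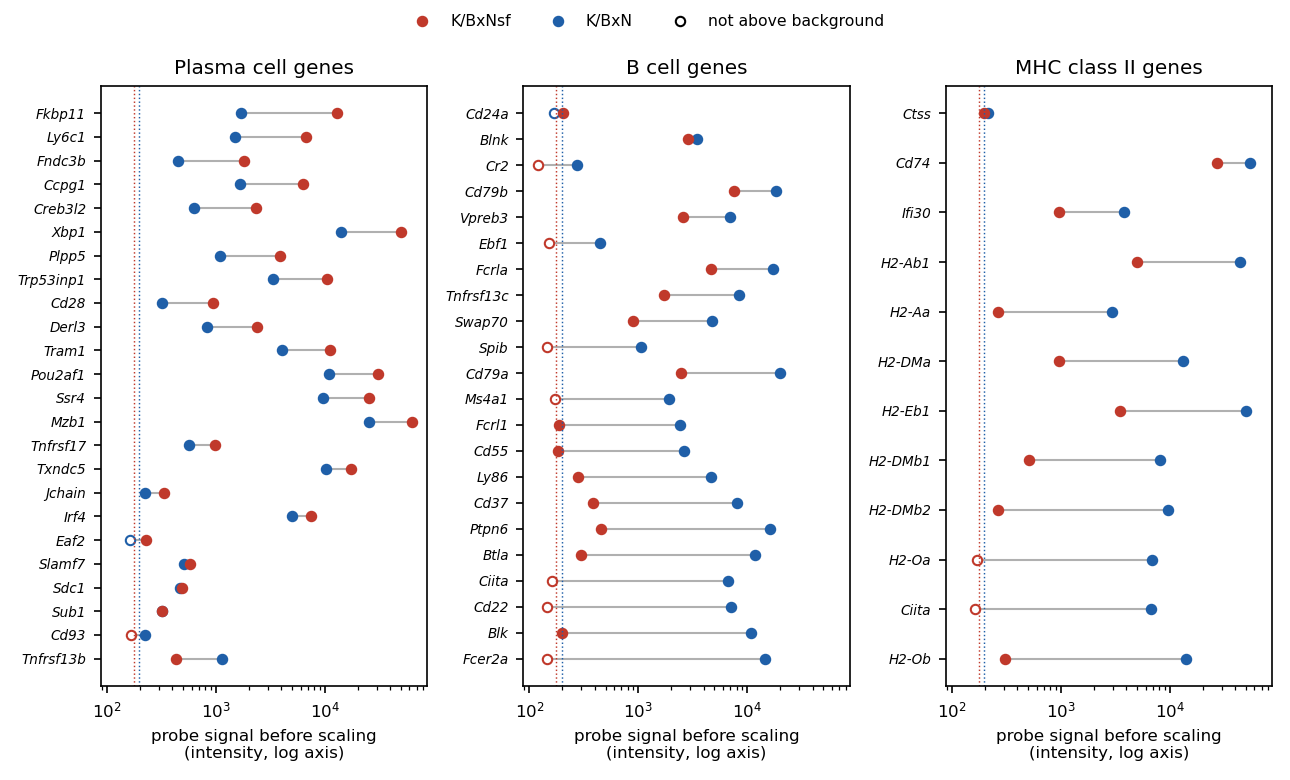
Probe signals before scaling (intensity, log axis) of the plasma cell, B cell and MHC class II genes measured on at least 1 array, with K/BxNsf in red and K/BxN in blue, 1 array each. Open circles are values not above background, and dotted lines mark the lowest measured signal of each array, 176.1 for K/BxNsf and 197.5 for K/BxN. The 10 MHC class II genes measured on both arrays and the 14 B cell genes measured on both arrays all had the lower signal in K/BxNsf, and 20 of 22 plasma cell genes had the higher.

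Among genes measured on both arrays, the 12 lowest in K/BxNsf included Il4i1, an amino acid oxidase of activated B cells, at 115-fold, Ephx1, microsomal epoxide hydrolase, at 88.3-fold, and Haao, an enzyme of tryptophan breakdown, at 44.5-fold. The homeobox gene Hhex was 43.5-fold lower, the sorting receptor gene Sorl1 41.3-fold, the inhibitory receptor gene Btla, which is in the B cell list, 39.4-fold, the membrane-shaping gene Bin1 38.2-fold and the interferon-inducible gene Samd9l 37.7-fold. On the K/BxN array alone, the activation marker gene Cd83 was at least 93.9-fold and the cannabinoid receptor gene Cnr2 at least 67.8-fold above its K/BxNsf level. The 12 genes highest in K/BxNsf were a mixed set. They included the chitinase-like gene Chil3, 23.2-fold higher, Pgam2, the muscle form of phosphoglycerate mutase, 20.2-fold, Serpinf1, 18.6-fold, Pnkd, 15.2-fold, the calgranulin gene S100a8, 14.7-fold, and the thyroglobulin gene Tg, 13.8-fold. The purine enzyme gene Ada was 13.3-fold higher, the fucosyltransferase gene Fut4 13.0-fold, the creatine kinase gene Ckb 12.5-fold, Pon3 12.3-fold and Maged1 12.2-fold. On the K/BxNsf array alone, Gpnmb was at least 30.9-fold, Retnlg at least 21.7-fold, Sgpp2, a sphingosine-1-phosphate phosphatase, at least 13.6-fold, Vegfa at least 12.7-fold and the desaturase family gene Fads3 at least 10.7-fold above its K/BxN level.

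Cell cycle genes were higher in K/BxNsf. Of 27 measured genes, 17 were at least 2-fold higher and 0 lower, with a median of 1.47 (0.73 to 2.32) and 0 of 10000 random lists above it. Tyms, thymidylate synthase, was 8.54-fold higher, the mitotic kinase genes Plk1 and Aurka 7.99-fold and 5.57-fold, and Cdca3 5.67-fold. The 6 replication licensing genes of the list, Mcm2, Mcm3, Mcm4, Mcm5, Mcm6 and Mcm7, were all under 2-fold, with log2 differences of 0.62, -0.195, 0.63, 0.51, 0.98 and 0.95. Before scaling, Mcm2, Mcm3, Mcm5 and Mcm7 had the lower signal in K/BxNsf, Mcm3 at 439.8 against 898.7. The cell cycle genes were higher on the array with the higher plasma cell and granulocyte genes and the lower B cell genes. Before scaling, 19 of the 27 signals were higher in K/BxNsf. Under median centring the median of the list was 0.70, which was 1.21 above the median of all genes, and 12 of the 27 were at least 2-fold higher.

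Genes of oxidative phosphorylation were moderately higher in K/BxNsf, with 12 of 33 at least 2-fold higher, 0 lower and a median of 0.82 (0.53 to 1.14), and 9 of 10000 random lists had a higher median. The complex I gene Ndufa1 was 6.79-fold higher, Ndufa5 3.54-fold and Ndufa4 3.33-fold. The ATP synthase gene Atp5o was measured on the K/BxNsf array alone, with a bound after scaling of 4.36-fold higher. Its signals before scaling were closer, 284.3 in K/BxNsf and 174.4 in K/BxN. Median centring put the list at 0.40, which was 0.92 above the median of all genes, against 0.68 above it under quantile normalization. Under median centring 6 of the 33 were at least 2-fold higher. Glycolysis genes had no common direction, with 3 of 14 at least 2-fold higher, 1 lower and a median of 0.30 that was -0.01 under median centring, or 0.51 above the median of all genes. Median centring gave 2 higher and 4 lower. In that list the hexokinase genes Hk2 and Hk3 were 7.77-fold and 3.13-fold higher and Tpi1 2.67-fold higher, while the glucose transporter gene Slc2a3 was 3.38-fold lower. Hk3 was under 2-fold with no background correction and Tpi1 with median centring. Of 32 ribosomal protein genes, 2 were at least 2-fold higher and 2 lower, and their median was 0.03. Those 4 were Rpl24, 3.61-fold, and Rplp0, 2.64-fold higher, the latter under 2-fold with median centring, and Rpl22, 4.06-fold, and Rps15, 2.23-fold lower. Under median centring the ribosomal median was 0.16, which was 0.68 above the median of all genes. A list median above that of all genes under median centring is therefore not by itself a sign of a rise.

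Several receptors that guide lymphocytes within the spleen were lower in K/BxNsf. Cxcr5, the receptor for the follicle chemokine CXCL13, was at least 49.4-fold lower, Ccr6 19.9-fold, S1pr4, a sphingosine-1-phosphate receptor, at least 11.7-fold and Gpr183, an oxysterol receptor, 9.37-fold. In the homing and adhesion list as a whole, 7 of 14 measured genes were at least 2-fold lower and 4 at least 2-fold higher, the latter being Cd9, Cxcr3, Cd44 and Selplg. The median was -0.83 (-2.67 to 1.82), and 17 of 10000 random lists had a lower one. It lay between -1.57, with signals at least 2 times the background, and -0.19, with no filter on dim probes.

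Genes of NF-kB and toll-like receptor signalling were lower in K/BxNsf, 9 of 16 by at least 2-fold against 1 that was higher, with a median of -1.05 (-1.88 to 0.19) and 4 of 10000 random lists below it. Tlr1 was at least 22.5-fold lower, the inhibitor gene Nfkbie 14.0-fold, Bcl3 9.85-fold and Relb at least 9.39-fold. The 1 higher gene was Ly96, which encodes the toll-like receptor partner MD-2, at 6.49-fold. The median was -1.68 under median centring, or -1.16 relative to the median of all genes. Of the interferon response genes, 9 of 28 were at least 2-fold lower and 4 higher, with a median of -0.34 (-1.09 to 0.35), and 371 of 10000 random lists were lower. Samd9l and Ifit3 were 37.7-fold and 5.18-fold lower and Oasl1 at least 4.10-fold lower, while Bst2 was 4.30-fold higher. This list stood at -1.14 under median centring, with 15 lower and 2 higher, or -0.62 relative to the median of all genes, and at -0.04 with signals at least 2 times the background.

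Costimulatory molecules and cytokines split as well. Cd40, the B cell receptor for T cell help, was 25.6-fold lower in K/BxNsf, Tgfb1 8.58-fold lower, and Ltb, lymphotoxin beta, and Il12a, the p35 subunit gene, at least 47.2-fold and 18.5-fold lower. The chemokine genes Ccl5 and Ccl4 were 5.99-fold and 4.13-fold higher, at signals of 752.4 against 342.1 and 446.3 against 293.7. Il10 was measured on the K/BxNsf array alone, with a bound after scaling of 3.38-fold higher at signals of 246.1 and 145.0. Cd274, which encodes the inhibitory ligand PD-L1, was 2.34-fold higher under quantile normalization, with signals of 2787 and 2058, and its log2 difference was 0.76 under median centring. Il6 was not above background on either array, at 136.6 and 153.8. Of the 9 measured genes of this list 4 were at least 2-fold higher and 3 lower, with a median of 0.55 that was -0.11 under median centring, or 0.41 above the median of all genes. Median centring gave 2 higher and 3 lower.

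Among survival genes, Bcl2 was measured on the K/BxN array alone and was at least 8.96-fold lower in K/BxNsf, while the death receptor gene Fas was 3.76-fold higher and Tnfrsf13c, the BAFF receptor gene, 3.51-fold lower. The 16 measured genes of the list had 3 at least 2-fold higher, 3 lower and a median of 0.02, which ranged from -0.56 to 0.40 over all settings. Germinal centre genes did not move as 1 group, since Bcl6, the master regulator of germinal centre B cells, was 15.1-fold lower and Mef2b 4.78-fold higher. Of the 6 measured, 3 were at least 2-fold higher and 1 lower, with a median of 0.94 (-3.91 to 2.26), and 399 of 10000 random lists were higher. Over all settings that median ranged from 0.17 to 1.57. With a detection p below 0.05, 3 of 9 were higher and 3 lower. With measurement on at least 1 array, 3 of 10 were higher and 4 lower. Immediate early and heat shock genes were mixed, with 8 of 21 at least 2-fold higher, 3 lower and a median of 0.43 (-0.25 to 1.64), or 0.20 to 0.61 over all settings. Fosb, Fos and Ier3 were 7.62-fold, 7.33-fold and 7.26-fold higher, whereas Dusp2, a MAP kinase phosphatase gene, was 6.96-fold lower.

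Markers of other cell types were examined beside these groups because a sort can hold other cells. Granulocyte genes stood out, with all 8 measured on both arrays at least 2-fold higher in K/BxNsf, 6 more measured on the K/BxNsf array alone and a median of 2.86 (1.16 to 4.53), and 0 of 10000 random lists were higher. S100a8 and S100a9 had signals of 7985 and 2843 in K/BxNsf against 988.5 and 769.2 in K/BxN. Chil3 was 23.2-fold higher, and Mpo, the myeloperoxidase of granulocyte precursors, was measured on the K/BxNsf array alone and was at least 9.72-fold higher. Erythroid genes were few, with Hba-a1, an alpha globin, 5.195-fold higher and Ctse 2.57-fold higher. Slc4a1, Tspan33, Mt2 and Nfe2 were measured on the K/BxNsf array alone at bounds of 2.44-fold, 1.89-fold, 1.76-fold and 1.615-fold, and Car2 on the K/BxN array alone at a bound of 1.225-fold. These bounds hold only after scaling. Of mast cell and basophil genes, Hdc was 6.98-fold and Il13 2.12-fold higher, and Prss34 was measured on the K/BxNsf array alone at a bound of 2.01-fold. The values of Ctse and Il13 were under 2-fold with median centring. Il13 had nearly equal signals before scaling, 199.5 in K/BxNsf and 199.1 in K/BxN.

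T cell genes had a median of 0.82 (0.34 to 1.76) over 10 measured genes, of which 4 were at least 2-fold higher and 1 lower. The median was 0.69 above the median of all genes, and under median centring it was -0.002, or 0.52 above it, while 7 of the 10 signals were lower in K/BxNsf before scaling. Cd8b1 was 5.75-fold and Thy1 3.39-fold higher, Cd3d was 2.20-fold higher, which was under 2-fold with median centring, and Cd2, which B cells of mice also express, was 11.2-fold lower. Cd3d had nearly equal signals before scaling, 609.2 in K/BxNsf and 596.4 in K/BxN. Foxp3, the transcription factor of regulatory T cells, was just above background on the K/BxN array at a signal of 200.7 and was not above background on the K/BxNsf array at 161.4, which gave no fold. Monocyte and macrophage genes had a median of 0.69 (-1.25 to 1.36), with 4 of 10 at least 2-fold higher and 2 lower. Under median centring their median was -0.04, or 0.48 above the median of all genes, with 1 higher and 2 lower. Lyz2 was 3.39-fold higher, Hmox1 and C1qb were 2.57-fold and 2.46-fold higher, both under 2-fold with median centring, and Apoe was 6.31-fold lower.

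The remaining marker lists had fewer than 5 measured genes and no percentile. Of natural killer and cytotoxic genes, Nkg7 was 3.37-fold and Ctsw 2.18-fold higher, Prf1, perforin, was 2.11-fold lower, and Klrd1 differed by a log2 value of 0.81, with signals before scaling of 292.3 in K/BxNsf and 342.1 in K/BxN. Klre1 and Klrg1 were measured on the K/BxNsf array alone at bounds of 1.87-fold and 1.78-fold, and on the K/BxN array alone were Tbx21, at a bound of 1.37-fold, and Klra1, which gave no fold. The bound of Klre1 came from scaling, since its signals were nearly equal, 188.3 in K/BxNsf and 187.9 in K/BxN. Ctsw was under 2-fold with median centring and Prf1 with no background correction. The signals of Ctsw before scaling were nearly equal, 625.6 in K/BxNsf and 614.1 in K/BxN. Of dendritic cell genes, Ly6d was 8.30-fold lower, Bst2 4.30-fold higher, Tcf4 and Cox6a2 differed by log2 values of 0.58 and -0.35, and Siglech was measured on the K/BxN array alone and gave no fold. Of progenitor B cell genes, Il7r was 1.93-fold lower, and Akap12, Vpreb1 and Rag1 were measured on the K/BxN array alone, at least 14.5-fold, 1.05-fold and 1.03-fold lower. Of stromal and endothelial genes, Pecam1 was 7.39-fold lower and Vcam1 differed by 0.06 on the log2 scale, with signals before scaling of 503.8 in K/BxNsf and 891.5 in K/BxN. Of 11 megakaryocyte and platelet genes with a probe, 0 were measured on either array.

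**Figure D3:**
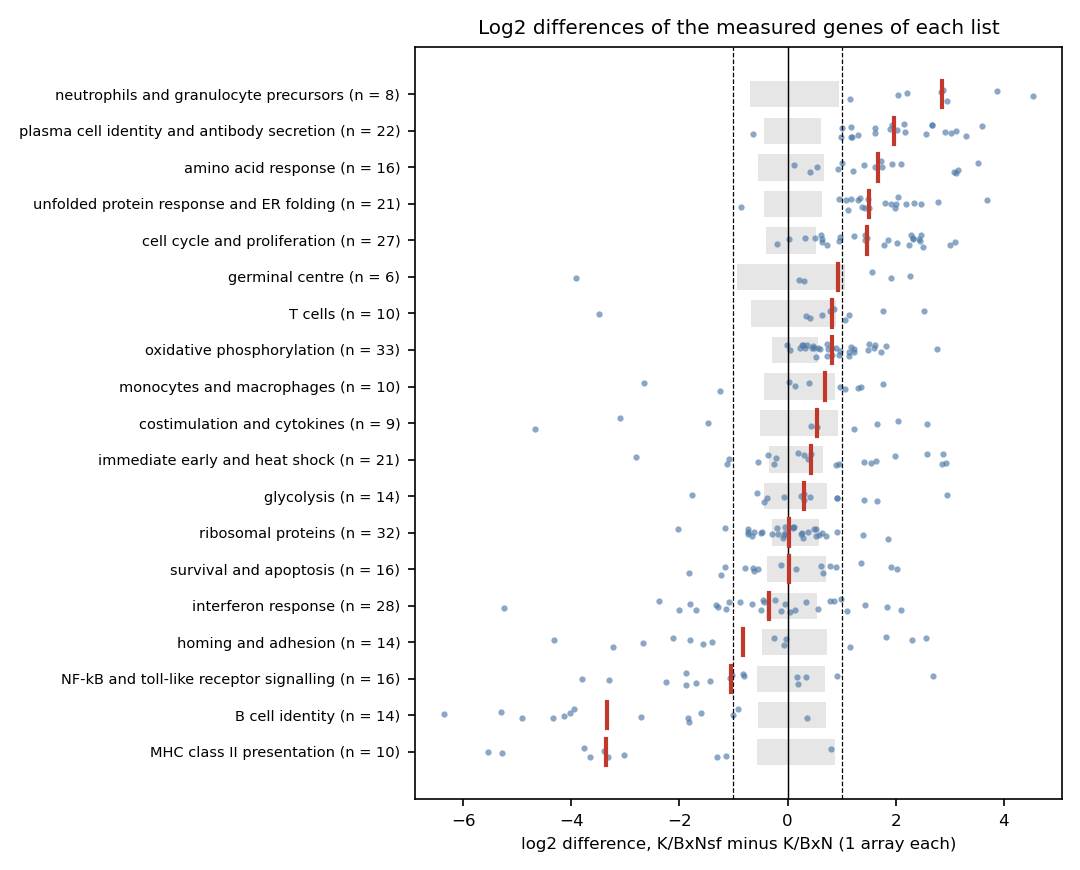
Log2 difference (K/BxNsf minus K/BxN, 1 array each) of each gene measured on both arrays, by list, for the 19 lists with at least 5 such genes. Points are genes, red bars the list medians, grey bands the central 95% of medians of 10000 random lists matched on size and expression, and dashed lines mark 2-fold. Neutrophil and plasma cell genes lie furthest to the right, with medians of 2.86 and 1.98, and B cell and MHC class II genes furthest to the left, at -3.33 and -3.36.

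Over the 19 lists with a percentile, 6 medians lay above and 4 below the central 95% of their random lists, where about 0.95 would be outside by chance. Some lists share genes and are not independent. The random lists draw each gene separately, while genes of a list can move together, so the 0.95 holds only for genes that vary independently.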

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

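The tests in this part were chosen after the results were seen, apart from the 10 alternatives chosen before, on whose list medians the tests of normalization draw. Probes with no gene name in the annotation used stood outside the comparison of genes, and they carried signal. Of 464 unnamed probes measured on both arrays, 151 were at least 2-fold apart, 78 higher and 73 lower in K/BxNsf, and 9 of the 50 brightest probes were unnamed. What these probes measure was not analysed here, and since no probe was named as an immunoglobulin gene, the level of antibody transcripts was not read from these arrays.

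The opposite movement of plasma cell genes against B cell and MHC class II genes was set against technical and biological readings. Background correction or normalization as the whole cause is argued against, because the smallest of the 3 list medians over all settings was still 1.75 in size. A larger share of B cells on the K/BxN array could account for the lower B cell and MHC class II genes in K/BxNsf, since 84.8% of them (28 of 33) were at least 2-fold lower, but a lower level per cell predicts the same and bulk RNA holds no value that separates them. Dilution of plasma cells by those B cells cannot be told apart as an account of the plasma cell genes, whose log2 differences had an SD of 0.99 against 0.47 per probe, because B cells express some of these genes and gene-specific folds would follow from dilution too. Whether a larger share of B cells also lowered homing, NF-kB, costimulation or survival genes in K/BxNsf was not tested. Age cannot be told apart from genotype, since the groups shared 0 ages, and a genotype effect stays open, untested.

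The granulocyte genes may come from granulocytes or their precursors in the K/BxNsf sort, although a gate on B220 and CD138 would be meant to exclude them. Of the 14 markers with a value, 100% were at least 2-fold higher or measured on the K/BxNsf array alone, none is shared with another list, and 8 were also measured on the K/BxN array, S100a8 at 988.5 against 7985. The share of 100% restates the pattern itself. Expression of these genes by the sorted cells predicts the same share, so it does not separate the 2 accounts. Normalization as the cause is argued against, since the list median was at least 2.17 under all settings. A lower share of the main cell type that raised markers of all other types alike is argued against. The granulocyte median was 2.04 above the T cell median and 2.17 above the macrophage median. With genes resampled 10000 times the lowest 95% limit of these differences, under median centring, was 0.99, which covers the choice of genes only. A lower share with other cell types in unlike proportions is not excluded, since only T cell and macrophage genes were compared. Erythroid and mast cell genes, with medians of 1.87 and 1.94 over 2 genes each, were not compared. Expression of these genes by the sorted cells themselves, as an effect of genotype or age, was not tested.

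The higher cell cycle genes could reflect dilution of dividing plasma cells by resting B cells on the K/BxN array. The median of the cell cycle list minus that of the plasma cell list was -0.51, and their intervals overlapped. Both intervals are wide spreads over genes, and more division per cell allows the same overlap, so it does not separate these accounts. Normalization as a part of the pattern cannot be told apart, since the median was 0.70 under median centring and stayed above 0 under all settings. More division per antibody-secreting cell in K/BxNsf stays open, untested.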

How the results depend on the processing

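The filter on signals of at least 2 times the background mean was chosen after the results were seen, and the other 10 alternatives before. For the 6 lists above and the 4 below the central range of their random lists, no median changed sign under any of the 11 alternatives. Among the other lists, the medians of T cell, macrophage, costimulation, glycolysis, survival and ribosomal protein genes changed sign under at least 1 alternative. No named gene at least 2-fold apart changed sign where it had a value. Values existed for 65 of 88 such genes under the filter on signals and for 88 under each other alternative. The 88 were all measured on both arrays, so these counts cover no bound of a gene measured on 1 array. Of 208 list medians under alternatives, 204 stayed within the interval of the main median. The exceptions all came from median centring, which gave 0.70 for cell cycle, -1.14 for interferon response, 0.40 for oxidative phosphorylation and -0.002 for T cells. The interval is a spread over genes and is wide for small lists, such as -3.91 to 2.26 for germinal centre genes. Staying within it therefore does not show that the processing had no effect. Median centring moved the median of all genes to -0.52, and it fixes each array by the level of its many probes near background, so the share of genes called higher depends on the scaling. It also gave 515 genes higher and 1925 lower. With no background correction there were 746 higher and 557 lower, all of the 557 among the 839 of the main setting. Measurement on at least 1 array gave 1393 lower and no filter 1398, which by construction add genes near background on the K/BxNsf array. Of 88 named genes at least 2-fold apart, 10 were under 2-fold with median centring, 9 with no background correction, 8 with the deposited log2 values, 6 with normexp on the signals alone, 2 with an offset of 50 and 0 with cyclic loess. The sizes of genes that stayed apart also shifted. Under median centring the log2 difference of Cd28 went from 3.12 to 2.38 and that of Ptprc from -1.27 to -2.09. With signals at least 2 times the background, 908 genes were higher and 577 lower. For the costimulation list that filter left under 5 genes and gave no median. The causes of the other shifts were not tested. Signal over background is a limit, since folds of genes dim on 1 array rest on signals close to the lowest measured, 176.1 and 197.5. No paired analysis was possible because each group had 1 array.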

Other observations

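The gene families and the X- and Y-linked genes in this part were chosen after the data were seen. Genes were grouped by the stem of their symbols, which gave 141 families with at least 6 measured genes. In 5 of them the median lay as far out as at most 5 of 10000 random lists matched on expression. By chance 0.141 families would, if genes varied independently. Of the 5 families, 1 on each side is described here. The Gimap genes, GTPases of lymphocyte survival, were lower in K/BxNsf, 5 of 6 by at least 2-fold with a median of -2.34 (-4.25 to -0.74) and 0 random lists below it. Gimap8 was 19.0-fold lower, at signals of 267.8 against 5126, and Gimap3 7.10-fold lower.

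On the higher side stood the kinesin genes, with 7 of 11 at least 2-fold higher, a median of 1.503 (-0.02 to 2.63) and 4 of 10000 random lists above it. The mitotic kinesin genes Kif2c, Kif4 and Kif18b were 7.36-fold, 6.17-fold and 5.73-fold higher, while Kif2a and Kif3a, which also serve in non-dividing cells, differed by log2 values of -0.02 and 0.16 and both had the lower signal in K/BxNsf before scaling. Kif11 and Kif22 are also in the cell cycle list. Outside the 5 families, the Alg genes, which build the glycans attached to secreted proteins, had 6 of 9 at least 2-fold higher and 0 lower, with a median of 1.48 and 13 random lists above it. The Cdca genes, of which Cdca3 and Cdca8 are in the cell cycle list, stood between the 5 and the Alg genes, with 9 above. Under the 7 scalings of the arrays the Gimap median lay between -2.71 and -1.91 and the kinesin median between 0.72 and 1.54. The Alg median lay between 0.74 and 1.48.

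Both samples are labelled male. Xist, the transcript of the inactive X chromosome, was above background on the K/BxN array at both of its probes, with signals of 345.4 and 248.8, and not on the K/BxNsf array, at 139.1 and 153.9. The Y-linked gene Eif2s3y was measured on both arrays, at 388.2 in K/BxNsf and 254.6 in K/BxN, and Kdm5d and Uty were above background on the K/BxN array at 216.2 and 206.6. On the K/BxNsf array Kdm5d and Uty were at 175.6 and 150.8. There Kdm5d missed the limit narrowly, with a detection p of 0.010025 against 0.01. No explanation was tested.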
